A study of Rattus norvegicus with 16 samples.

How the data were processed

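Ovaries of 8 rats, 4 labelled CON and 4 labelled VCD, gave 16 libraries, an m6A immunoprecipitation (IP) and an input library per rat. Poly(A) RNA was fragmented, incubated with an m6A antibody and made into stranded libraries, per the labels' protocols. Titles number the rats, so replicates were taken as separate animals. The organism label is rat, while the series text speaks of mice and the submitters' processing notes name the human build GRCh38. The files hold rat gene identifiers, and among 15862 symbols shared with the gene reference for GRCr8, 0 had a start within 1000 bases of the one given there. The build is therefore not given in the sources used here, and coordinates are printed as in the files, counted from 1.

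FPKM per gene and input library came from the authors, per the file headers. The same table gives a fold ratio of group means and its log2 value, made by the authors, per the file headers. It also gives p-values and q-values of the authors' test, whose kind is not given in the sources used here. The submitters' processing notes list fastp 0.19.4, HISAT2 2.0.4, StringTie 2.1.2, edgeR 4.1 and HOMER 4.10, with no role or order. Peak lists give a log2 enrichment of IP over input per peak, with p-values and adjusted p-values, made by the authors from pooled replicates, per the file headers. The deposited table of differential peaks gives the log2 enrichment in VCD and in CON, their difference and its p-value. The peaks listed with a p-value all had one under 0.05, and the table marks as significant those with an absolute log2 change of at least 1, per the file headers. The peak caller is not given in the sources used here. FPKM values keep no read totals, low values were not whole multiples of 1 step, and so the depth and its counting error are unknown. No housekeeping gene of 11 checked was listed at 0 in any library.

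Genes with a mean of at least 0.5 FPKM over the 8 input libraries (14978 of 22663) were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, with treatment as the only term. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05, with no minimum fold. Log2 changes are on the log2(FPKM + 1) scale and understate changes of low genes. Gene lists with at least 5 tested members (23 of 25) were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. Under the stricter filter the same lists were tested with whatever members remained. The 7 genes named in the series text were compared by exact permutation tests of the 70 arrangements of 8 libraries, adjusted over the 7. Peaks were compared by an overlap of at least 1 base on the same strand (bedtools 2.31.1). The direction of m6A and expression changes was compared with Fisher's exact test and Spearman's rho (Python 3.11.15, scipy 1.17.1). The limma and list tests, the peak overlap and the comparison of m6A and expression directions were fixed before the data were examined. So were the gene lists, the alternatives named below and the rule for named genes. Not in that plan were the exact permutation tests, of the 7 genes and of RNA content, and Fisher's tests of peaks by list.

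The rule named the 7 genes of the series text and the 10 largest rises and 10 largest falls among called genes. These had to separate the groups, reach a mean of at least 1 FPKM in the higher group and have a gene symbol. It also took up to 4 members of each list with the smallest p-values, and the 5 largest rises and 5 largest falls among significant peaks with an adjusted p under 0.05. Cyp19a1, Nlrp5, Dppa3, Astl, Tcl1a, AC135142.1 and the genes of the lists under other observations that lie outside the rule were chosen after their values were seen. List members missing from the tables used, such as Igf2bp1, Pecam1, Col1a2, Ucp1, Oosp1 and E2f1, were not analysed here.

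On simulated values for 14978 genes, the gene test recovered 88 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2, and 6 of the 193 genes it called were unchanged. Of the lists, 2 of 2 shifted by 0.3 and 0 of 21 unshifted ones were called. Changed genes and list members were drawn from genes with a mean log2(FPKM + 1) of at least 2. Recovery among lower genes, which were also tested in the real data, was therefore not measured. Simulated genes varied independently, whereas members of the real lists were correlated (estimated at 0.39 in the oocyte list). The simulation therefore cannot tell how often camera makes false calls in the real lists. CON and VCD share replicate numbers through a batch label, whose meaning is not given in the sources used here. The number was used as a block in 1 alternative and not in the main fits. Deviations of same-numbered libraries from their group means correlated at -0.01, -0.09, 0.01 and -0.07, and those of other pairs at up to 0.27. These values gave no sign of a pairing by number.

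Alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, quantile normalization, scaling to a common median, the replicate number as a block, each library left out, and the authors' q-values. For peaks they were a fold enrichment of at least 4, an adjusted p under 0.001, stricter overlaps, an adjusted p under 0.05, no minimum fold, all listed peaks and 1 peak per gene. Count tests were left out because the tables hold no counts, and the IP libraries were left out of the expression fit because no expression values of theirs were used here. Motif analysis needs a genome of the same build and was not done.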

Results

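The ovary samples came from 8 rats, 4 in a group labelled CON and 4 given VCD (4-vinylcyclohexene diepoxide, an industrial epoxide known to destroy small ovarian follicles). Each rat gave 2 libraries, 1 of poly(A) RNA fragments pulled down with an antibody against N6-methyladenosine (m6A, a methyl mark on adenosines of mRNA) and 1 of the input fragments, 16 libraries in all. Expression values were analysed for the 8 input libraries as FPKM of 22663 genes. The read depth is unknown, since FPKM values hold no totals, and sums per library lay between 403808.8 and 421627.8 FPKM. Genes with at least 1 FPKM numbered 13768 ± 101 (SD, n = 4) in CON and 13396 ± 145 (SD, n = 4) in VCD (exact permutation test, 2-sided, p = 0.0286; adjusted p = 0.0571 over 4 measures of RNA content). Genes typed as ribosomal RNA summed to 12.8 ± 8.17 FPKM in CON and 42.0 ± 14.1 FPKM in VCD (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0571). Small nuclear RNA genes summed to 62.8 ± 7.66 FPKM in CON and 84.0 ± 20.8 FPKM in VCD (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.0571).

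The comparison of input libraries asks which transcripts differ between VCD and CON ovaries. Oocyte transcripts made up 6 of the 10 largest falls. Padi6, a part of the oocyte's cytoplasmic lattices, fell from 9.56 ± 2.30 FPKM in CON to 1.19 ± 0.476 FPKM in VCD (SD, n = 4 each; log2 change -2.27 ± 0.19 SE, limma adjusted p = 0.00478). Zp3, which encodes a zona pellucida protein, fell from 6.69 ± 1.28 to 0.928 ± 0.498 FPKM (log2 change -2.02 ± 0.20 SE, limma adjusted p = 0.00493). Gdf9, an oocyte growth factor that acts on granulosa cells, fell from 6.48 ± 1.78 to 1.22 ± 0.167 FPKM (log2 change -1.73 ± 0.17 SE, limma adjusted p = 0.00493). Amh, the anti-Müllerian hormone made by granulosa cells of small growing follicles, fell from 59.5 ± 11.7 to 13.5 ± 7.63 FPKM (log2 change -2.19 ± 0.32 SE, limma adjusted p = 0.0297).

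Npm2, a histone chaperone of the egg, fell by 1.66 on the log2 scale, and Ooep and Nlrp14, both maternal-effect genes, fell by 1.62 and 1.33. Ccno, a cyclin-like gene needed for multiciliated cells, fell by 1.57, Urad, an enzyme of urate breakdown, by 1.44, and Ly6g6e by 1.30. Limma adjusted p values of these 6 genes lay between 0.00493 and 0.0429. Among the falls, Padi6, Zp3, Gdf9, Ooep, Urad and Nlrp14 kept limma adjusted p values under the threshold when any 1 library was left out. Without CON 2 and VCD 4 only Padi6 of the 10 falls kept its call, with Zp3 at 0.0698, Gdf9 at 0.0882, Ooep at 0.0656, and Urad and Nlrp14 at 0.0987. Without VCD 2 and VCD 4 Padi6, Zp3 and Ooep kept theirs, with Gdf9 at 0.105, Urad at 0.103 and Nlrp14 at 0.123. The call of Amh was lost without CON 1 (adjusted p = 0.107), CON 2 (0.0836), CON 3 (0.110), VCD 2 (0.0596) or VCD 4 (0.0855). Npm2 lost its call without CON 1 (0.0809), CON 3 (0.0756), VCD 2 (0.0548) or VCD 4 (0.0781), and Ccno without CON 1 (0.0573) or VCD 4 (0.0619). Ly6g6e kept it only without VCD 1, its adjusted p lying between 0.0502 (without VCD 3) and 0.128 (without CON 1) when CON 1, CON 2, CON 3, CON 4, VCD 2, VCD 3 or VCD 4 was left out. With the replicate number as a block it had an adjusted p of 0.0787. With no filter on low values the calls of Amh (0.0772), Npm2 (0.0639) and Ly6g6e (0.0938) were lost, and at a mean of at least 5 FPKM those of Amh (0.0597) and Ly6g6e (0.0665).

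Among the rises, Errfi1, a feedback inhibitor of the EGF receptor, went from 20.3 ± 2.38 FPKM in CON to 56.4 ± 10.2 FPKM in VCD (SD, n = 4 each; log2 change 1.42 ± 0.14 SE, limma adjusted p = 0.00493). Nr4a3, an orphan nuclear receptor of the immediate-early class, rose from 0.923 ± 0.265 to 3.92 ± 0.946 FPKM (log2 change 1.34 ± 0.16 SE, limma adjusted p = 0.0126). Per1, a core gene of the circadian clock, rose from 23.2 ± 1.76 to 40.6 ± 2.74 FPKM (log2 change 0.79 ± 0.08 SE, limma adjusted p = 0.00493). Ttc39a rose by 1.13 on the log2 scale, Arrdc3, an arrestin-domain gene, by 0.83, Dusp16, a phosphatase of MAP kinases, by 0.82, and Lipg, the endothelial lipase, by 0.68. Tmco4 rose by 0.63, Clec2d2 by 0.56 and Dusp14l1 by 0.53, the last a copy of Dusp14.

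Errfi1, Nr4a3 and Per1 kept their calls when any 1 library was left out, and the other 7 rises did not. With 2 libraries left out only Errfi1 of the 10 rises kept its call, with Nr4a3 at a limma adjusted p of 0.0882 and Per1 at 0.0987 without CON 2 and VCD 4, and both at 0.103 without VCD 2 and VCD 4. Without CON 1 those 7 had limma adjusted p values from 0.0872 (Dusp16) to 0.128 (Tmco4), without CON 2 from 0.0557 (Dusp14l1) to 0.107 (Dusp16 and Tmco4), and without CON 3 from 0.0756 (Ttc39a) to 0.130 (Tmco4). Without VCD 4 all of them but Arrdc3 were lost, from 0.0718 (Dusp14l1) to 0.127 (Lipg), and without VCD 2 all but Ttc39a, from 0.0548 (Arrdc3 and Dusp14l1) to 0.0786 (Dusp16). Without VCD 1 Arrdc3, Dusp16, Lipg, Tmco4 and Clec2d2 were lost, from 0.0503 (Lipg) to 0.0860 (Tmco4). Lipg was also lost without CON 4 (0.0587) or VCD 3 (0.0530). With the replicate number as a block, Arrdc3, Dusp16 and Tmco4 had an adjusted p of 0.0721, Lipg of 0.0665, Clec2d2 of 0.0736 and Dusp14l1 of 0.0758. At a mean of at least 5 FPKM all 7 were lost, from 0.0597 (Ttc39a) to 0.0665 (Lipg). With no filter Ttc39a (0.0714), Arrdc3 (0.0549), Dusp16 (0.0772), Lipg (0.0772) and Tmco4 (0.0639) were lost, and under quantile normalization Dusp16 (0.0529) and Lipg (0.0528).

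**Figure D1:**
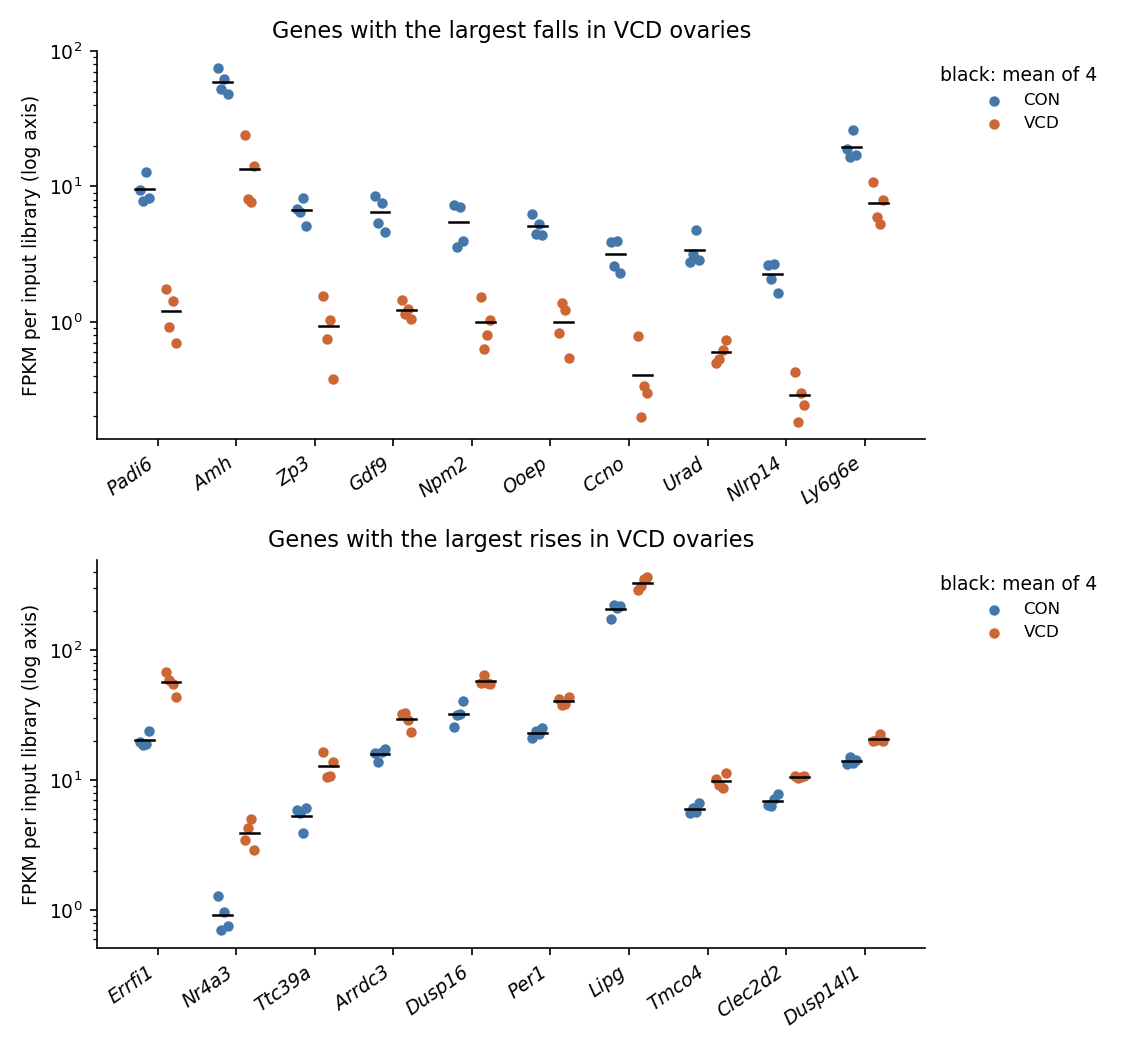
FPKM per input library (log axis) of the 10 genes with the largest falls and the 10 with the largest rises in VCD, with blue points for 4 CON libraries, orange points for 4 VCD libraries and black lines for means. For each gene the 4 VCD libraries lie on one side of the 4 CON libraries.

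In all, 67 of 14978 tested genes changed at a limma adjusted p under 0.05, 16 higher and 51 lower in VCD. The VCD and CON libraries did not overlap in 11.85% of the tested genes, where chance gives 2.86% on average over arrangements of the libraries. Of these genes 340 were higher and 1435 lower in VCD, and the median log2 change over all tested genes was -0.063. Genes vary together, so the distance from 2.86% is not a test. Scaling each library to a common median gave 59 genes, 21 higher and 38 lower. The replicate number as a block gave 31 genes, 22 of them among the 67, and the filter at a mean of at least 5 FPKM gave 3 genes. Leaving out 1 library gave 12 genes without CON 1, 23 without CON 2, 22 without CON 3, 29 without VCD 2, 115 without VCD 3 and 13 without VCD 4. Without VCD 2 and VCD 4, the libraries with the highest ribosomal RNA sums, 7 genes passed, and without CON 2 and VCD 4, 3 genes. The authors' deposited table held 1038 genes with a q-value under 0.05, 396 higher and 642 lower, which included all 67.

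Of the 20 oocyte genes tested, 12 fell and none rose over all genes, and 18 fell when adjusted over the list alone. With the replicate number as a block, 4 of the 12 lost their calls, Nlrp5 (adjusted p = 0.0620), Dppa3 (0.0665), Astl (0.0589) and Tcl1a (0.0571). H1f8, the linker histone of oocytes, fell from 2.62 ± 0.521 to 0.491 ± 0.0997 FPKM and Nlrp14 from 2.25 ± 0.491 to 0.288 ± 0.104 FPKM (SD, n = 4 each; limma adjusted p = 0.00493 for both), and both kept their calls when any 1 library was left out. Without CON 2 and VCD 4 both had an adjusted p of 0.0987, and without VCD 2 and VCD 4 H1f8 had 0.111 and Nlrp14 0.123. The list's median log2 change was -1.10 (camera adjusted p = 8.9e-20; adjusted p = 0.211 with an estimated correlation). Of 37 oocyte entries with any value, filtered ones included, 34 had a lower mean in VCD. The ribosomal RNA sum described above was higher in the same VCD libraries.

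Granulosa genes did not pass camera as a list, and fry for members in either direction gave an adjusted p of 0.0145. Amh fell, and the other 20 tested members did not pass over all genes, while 3 fell when adjusted over the list alone (median log2 change -0.11, camera adjusted p = 0.601; adjusted p = 0.840 with an estimated correlation). Ihh, the hedgehog ligand of granulosa cells, measured 13.1 ± 4.52 FPKM in CON and 6.86 ± 1.12 FPKM in VCD, and Fshr, the FSH receptor, 4.27 ± 0.983 and 2.70 ± 0.543 FPKM (SD, n = 4 each; limma adjusted p = 0.107 and 0.157). Cyp19a1, the aromatase gene, chosen after its values were seen, measured 25.2 ± 21.8 FPKM in CON and 79.0 ± 45.7 FPKM in VCD (limma adjusted p = 0.188).

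Among genes of cell division, Spc25, an outer kinetochore protein, fell from 3.66 ± 0.849 to 1.35 ± 0.372 FPKM, and Kif2c, a microtubule depolymerase of the centromere, from 4.38 ± 1.04 to 1.91 ± 0.354 FPKM (SD, n = 4 each; limma adjusted p = 0.0455 and 0.0496). The other 27 of 29 tested kinetochore and spindle genes did not pass over all genes, and 24 of the 29 fell when adjusted over the list alone (median log2 change -0.75, camera adjusted p = 3.2e-14; adjusted p = 0.212 with an estimated correlation). None of 18 proliferation genes passed over all genes, and 17 fell when adjusted over the list alone (median log2 change -0.61, camera adjusted p = 2.3e-10; adjusted p = 0.212 with an estimated correlation). Top2a, topoisomerase II of dividing cells, measured 10.9 ± 2.30 FPKM in CON and 4.58 ± 1.35 FPKM in VCD (limma adjusted p = 0.0544). As a block the replicate number gave Top2a an adjusted p of 0.0426, Spc25 of 0.0620 and Kif2c of 0.0664. Top2a passed without CON 4 (0.0495) or VCD 3 (0.0402). Kif2c lost its call without CON 1 (0.111), CON 2 (0.117), CON 3 (0.143), CON 4 (0.0587), VCD 1 (0.0829), VCD 2 (0.0934) or VCD 4 (0.134). It was also lost under quantile normalization (0.0812), scaling to a common median (0.0599), no filter (0.0938) and a pseudocount of 0.1 (0.0504). Spc25 lost its call without CON 1 (0.128), CON 2 (0.120), CON 3 (0.1502), VCD 1 (0.0826), VCD 2 (0.0910) or VCD 4 (0.134), and under the same 4 alternatives (0.0773, 0.0538, 0.0900 and 0.0504).

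Among genes for repair of DNA double-strand breaks and crosslinks, H2ax, the histone variant phosphorylated at breaks, fell from 33.6 ± 2.81 to 23.8 ± 1.11 FPKM (SD, n = 4 each; limma adjusted p = 0.0429). The other 27 of 28 tested members did not pass over all genes, and 9 fell when adjusted over the list alone (median log2 change -0.29, camera adjusted p = 6.8e-07; adjusted p = 0.212 with an estimated correlation). Rad50, of the complex that senses breaks, measured 6.07 ± 0.293 and 3.88 ± 0.620 FPKM in CON and VCD (limma adjusted p = 0.0689). For H2ax the replicate number as a block gave an adjusted p of 0.0904, and scaling to a common median gave 0.0826. Its call was kept only without VCD 3, and was lost without CON 1 (0.112), CON 2 (0.117), CON 3 (0.111), CON 4 (0.0587), VCD 1 (0.0829), VCD 2 (0.0871) or VCD 4 (0.127). At a mean of at least 5 FPKM H2ax had an adjusted p of 0.0665 and the list a camera adjusted p of 0.0681.

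Targets of p53 had a median log2 change of 0.05, with none of 18 tested past the threshold over all genes and 1 higher when adjusted over the list alone (camera adjusted p = 0.0200; adjusted p = 0.271 with an estimated correlation). In value 10 of the 18 were higher and 8 lower. Btg2, also in the immediate-early list under other observations, changed by 1.21 on the log2 scale (limma adjusted p = 0.255). It measured 18.1 ± 2.30 FPKM in CON and 55.5 ± 38.7 FPKM in VCD (SD, n = 4 each). The list was not tested without Btg2. Gadd45a, a growth arrest gene, measured 186 ± 31.4 FPKM in CON and 282 ± 19.5 FPKM in VCD (SD, n = 4 each; limma adjusted p = 0.0747). The call of the p53 list was lost without CON 4 (0.0570) or VCD 3 (0.0858), and its mean log2 change went from 0.11 to 0.07 without VCD 1. NRF2 and antioxidant genes had a median log2 change of 0.06, with none of 19 past the threshold over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.211 with an estimated correlation). Quantile normalization gave this list an adjusted p of 0.319. Apoptosis genes (adjusted p = 0.722), xenobiotic and epoxide metabolism genes (0.390, with a median below 0 and a camera direction above 0), PI3K and follicle activation genes (0.601), meiotic prophase genes (0.601) and inflammatory cytokine genes (0.0594) did not pass camera. The inflammatory list passed without CON 3 (0.0162) or VCD 3 (0.0320), with no filter (0.0157) and at a mean of at least 5 FPKM (0.0241).

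Of the 11 endothelial genes tested, 11 were higher in value in VCD, none passed over all genes and 7 rose when adjusted over the list alone (median log2 change 0.33, camera adjusted p = 3.4e-08; adjusted p = 0.211 with an estimated correlation). Emcn, an endothelial sialomucin, measured 33.0 ± 3.62 FPKM in CON and 47.6 ± 4.25 FPKM in VCD, and Kdr, a VEGF receptor, 17.3 ± 4.37 and 25.3 ± 2.72 FPKM (SD, n = 4 each; limma adjusted p = 0.0631 and 0.127). Smooth muscle genes were higher in value in 10 of 10, none past the threshold over all genes and 0 when adjusted over the list alone (median log2 change 0.24, camera adjusted p = 0.00144; adjusted p = 0.445 with an estimated correlation). Their mean log2 change was 0.22, and 0.09 without VCD 4, and the call was lost without VCD 2 and VCD 4 (0.0579) and without CON 2 and VCD 4 (0.167). Stroma and fibroblast genes were lower in 14 of 15, none past the threshold over all genes and 0 when adjusted over the list alone (median log2 change -0.32, camera adjusted p = 0.0125; adjusted p = 0.465 with an estimated correlation). Dcn, the matrix proteoglycan decorin, measured 186 ± 29.1 and 134 ± 21.4 FPKM in CON and VCD (limma adjusted p = 0.142). The stroma call was lost without CON 1 (0.0576) or VCD 2 (0.111), without VCD 2 and VCD 4 together (0.469), and with directional fry (0.125).

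Theca and interstitial steroidogenic genes were higher as a list (median log2 change 0.23, camera adjusted p = 0.0104; adjusted p = 0.211 with an estimated correlation). None of the 19 tested passed over all genes. Adjusted over the list alone, 3 fell, namely Hhip, Gli1 and Ptch1, all targets of hedgehog signalling. Gli1 measured 4.43 ± 1.90 FPKM in CON and 1.74 ± 0.451 FPKM in VCD, and Cyp51, an enzyme of cholesterol synthesis, 69.2 ± 17.2 and 109 ± 31.4 FPKM (SD, n = 4 each; limma adjusted p = 0.110 and 0.179). Quantile normalization gave the theca list an adjusted p of 0.387 and scaling to a common median gave 0.127, and without VCD 2 and VCD 4 it was 0.0638. The list's mean log2 change was 0.11, against 0.06 without CON 1 and 0.17 without CON 4. Adipocyte genes passed as a list (6 tested, median log2 change 0.14, camera adjusted p = 0.0275; adjusted p = 0.211 with an estimated correlation). In value 5 were higher and 1, Fabp4, lower, at 89.1 ± 107 FPKM in CON and 33.7 ± 13.0 FPKM in VCD (SD, n = 4 each; limma adjusted p = 0.489). Fabp4 stood at 249 FPKM in CON 1, against 28.0 to 42.5 FPKM in the other CON libraries. Cfd, the complement factor adipsin, rose from 21.4 ± 0.741 to 28.2 ± 0.921 FPKM (limma adjusted p = 0.0429; 0.113 with the replicate number as a block), and 1 gene rose when adjusted over the list alone. Each library left out in turn ended the call of Cfd, with adjusted p values of 0.152 (without CON 1), 0.120 (CON 2), 0.112 (CON 3), 0.0621 (CON 4), 0.0886 (VCD 1), 0.0793 (VCD 2), 0.0502 (VCD 3) and 0.0988 (VCD 4), and at a mean of at least 5 FPKM it was 0.0665 for Cfd. The adipocyte list was lost without CON 4 (0.0727) or VCD 4 (0.111), under quantile normalization (0.0555), under scaling to a common median (0.113), without VCD 2 and VCD 4 (0.132), without CON 2 and VCD 4 (0.101), and at a mean of at least 5 FPKM (0.0666), where only Cfd, Fabp4 and Lipe remained. The list's mean log2 change was 0.02, and between -0.08 (without CON 4) and 0.14 (without CON 1) with 1 library left out.

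Corpus luteum genes (camera adjusted p = 0.0750), macrophage genes (0.601), lymphocyte genes (0.199) and oviduct and surface epithelium genes (0.265) did not pass. Epithelial markers were highest in CON 2, at a mean log2 value of 2.78, against 1.41 to 2.31 in the other libraries. The epithelial list passed without CON 4 (0.0243), and the corpus luteum list without CON 4 (0.00963) or VCD 2 (0.0499). Of the red cell genes, Alas2, an enzyme of haem synthesis, measured 0.697 ± 0.316 FPKM in CON and 1.15 ± 0.576 FPKM in VCD, and Hbb, a globin, 92.2 ± 27.3 and 73.8 ± 35.8 FPKM (SD, n = 4 each; limma adjusted p = 0.427 and 0.567).

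**Figure D2:**
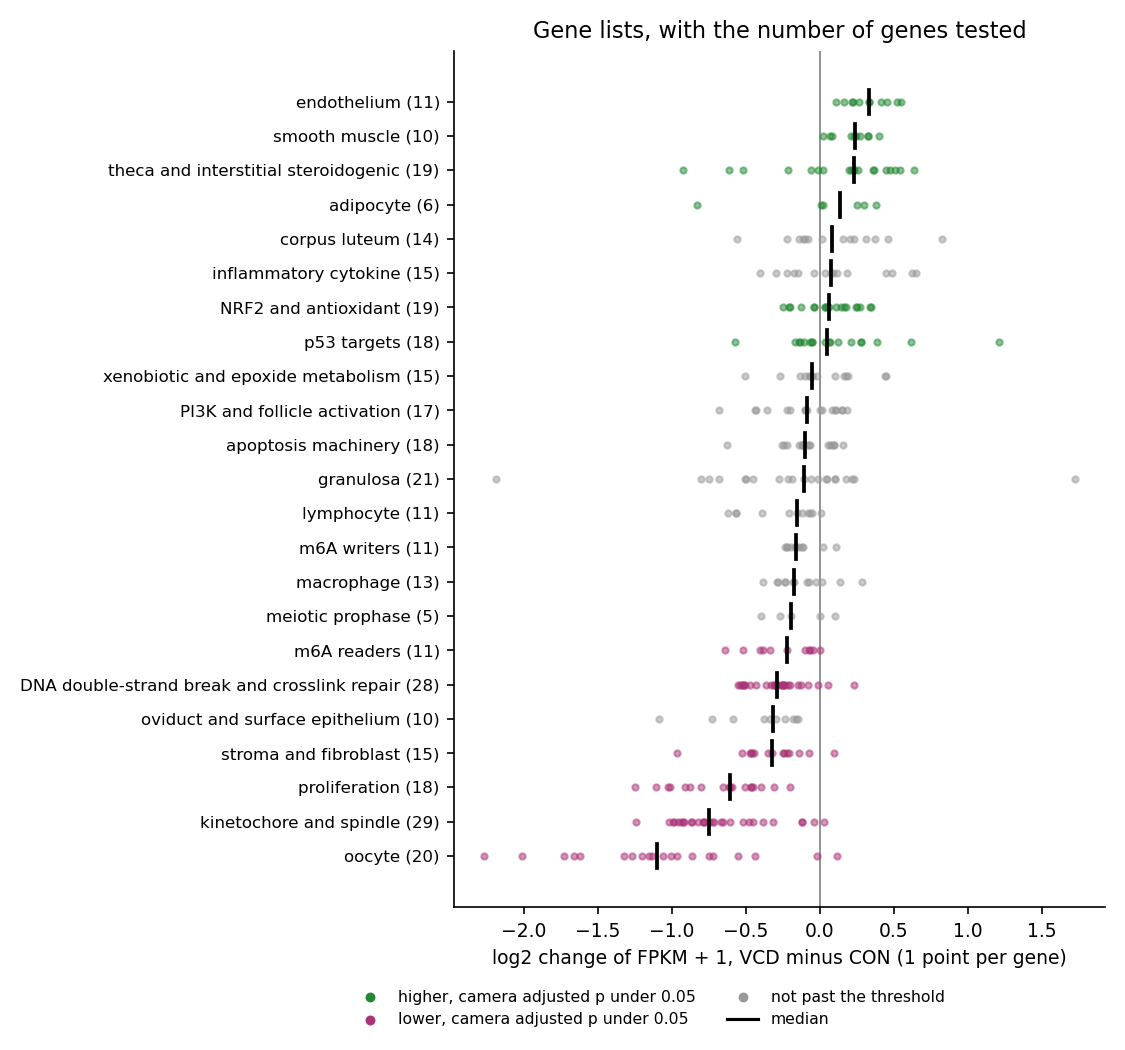
Log2 change of FPKM + 1 (VCD minus CON, 4 libraries each) of each tested gene in the 23 lists tested with camera, with black bars for medians and the number of tested genes in parentheses. Green lists were higher and purple lists lower at the preset correlation, from a median of -1.10 in the oocyte list to 0.33 in the endothelial list, and none of the 12 passed with an estimated correlation.

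The study's question concerned m6A enzymes, the m6A reader Igf2bp3 and mRNAs for chromosome segregation and repair in oocytes. Igf2bp3 was listed at 0.215, 0.138, 0.303 and 0.197 FPKM in CON 1 to 4, and at 0.120 FPKM in VCD 1 and 0 in VCD 2, VCD 3 and VCD 4 (exact permutation test, 2-sided, p = 0.0286, n = 4 each). Polq, a polymerase of end joining, measured 0.323 ± 0.0693 FPKM in CON and 0.139 ± 0.0366 FPKM in VCD, Cenpa, the centromeric histone, 1.96 ± 0.506 and 0.875 ± 0.298 FPKM, and Bub1, a spindle checkpoint kinase, 3.49 ± 0.696 and 1.28 ± 0.468 FPKM (SD, n = 4 each; exact permutation p = 0.0286 for each). For these 4 genes the adjusted exact p over the 7 genes was 0.05, and 0.0286 is the smallest p that 4 against 4 libraries can give. The values are of whole ovaries and not of oocytes alone. Fewer cells holding these mRNAs and less of the mRNAs per cell cannot be told apart in them. Over all genes, limma gave Cenpa an adjusted p of 0.0966 and Bub1 of 0.0522, while Igf2bp3 and Polq lay below the filter. Bub1 passed with the replicate number as a block (0.0479) and without VCD 3 (0.0402). Its gene spans chromosome 3, 120373604 to 120404910 on the minus strand, on a build not given in the sources used here.

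Mettl3, the catalytic m6A methyltransferase, measured 32.6 ± 2.55 FPKM in CON and 33.0 ± 1.81 FPKM in VCD, and the demethylases Fto and Alkbh5 19.9 ± 1.28 and 20.2 ± 0.527 FPKM in CON and 20.4 ± 2.07 and 20.6 ± 1.67 FPKM in VCD (SD, n = 4 each; exact permutation p = 0.743, 0.686 and 0.743). These differences were smaller than the spread between libraries. None of 11 m6A writers passed over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.106; adjusted p = 0.594 with an estimated correlation). With no filter on low values the writers were lower as a list (camera adjusted p = 0.0234). The 11 tested m6A readers were lower as a list, with none past the threshold over all genes and 5 lower when adjusted over the list alone (median log2 change -0.22, camera adjusted p = 0.0104; adjusted p = 0.403 with an estimated correlation). Rbmx, an RNA-binding protein of the nucleus, measured 28.6 ± 1.88 and 18.2 ± 3.11 FPKM, and Fmr1, the fragile X protein gene, 6.33 ± 0.645 and 4.14 ± 0.832 FPKM in CON and VCD (SD, n = 4 each; limma adjusted p = 0.0580 and 0.102). Rbmx passed without VCD 3 (0.0284), and the readers' list lost its call without VCD 2 and VCD 4 (0.0522). In the authors' deposited table the log2 ratio of Igf2bp3 was -2.83 with a q-value of 0.280, that of Cenpa -1.16 with 0.00677, that of Bub1 -1.45 with 7.7e-05 and that of Polq -1.22 with 0.00328.

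**Figure D3:**
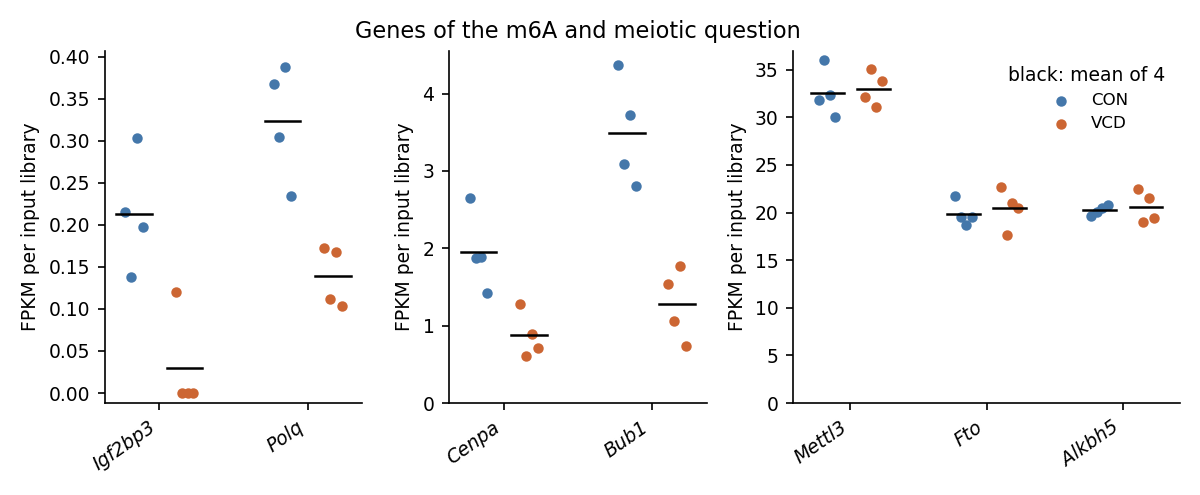
FPKM per input library of Igf2bp3, Polq, Cenpa, Bub1, Mettl3, Fto and Alkbh5, with blue points for 4 CON libraries, orange points for 4 VCD libraries and black lines for means. In the first 4 genes each VCD library lies below each CON library, and in the other 3 the groups overlap.

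The peak lists describe where m6A lay in each group. CON held 22316 peaks in 13150 genes and VCD 21528 peaks in 12841 genes, each list made by the authors from the pooled libraries of 1 group, so there is no test between groups. Peaks at stop codons were the largest class, 32.4% of CON and 32.9% of VCD peaks, followed by exonic peaks (27.3% and 27.1%), peaks in the 3' UTR (20.3% and 19.97%) and at start codons (13.8% in each). Median log2 enrichment of IP over input, the authors' value per peak, was 2.31 in CON and 2.40 in VCD. At least 1 base on the same strand was shared by 88.0% of CON peaks with a VCD peak and by 91.7% of VCD peaks with a CON peak. With overlap of at least 50% of both peaks required, the shares were 76.4% and 79.2%. Of the oocyte genes, 17 had a peak in CON and 9 in VCD, whereas 29 kinetochore and spindle genes had a peak in each group. Expression fell further in the oocyte list, with a median log2 change of -1.10 against -0.75 in the kinetochore and spindle list. These peak counts therefore cannot tell loss of m6A from loss of the transcripts, and the contrast was not tested. Among differential peaks listed by the authors, oocyte genes with a higher peak numbered 2 and those with a lower peak 0. Igf2bp3 had no peak in either list, Polq 3 in CON and 0 in VCD, Cenpa 2 and 1, Bub1 2 and 2, Mettl3 2 and 2, Fto 2 and 3, and Alkbh5 2 and 1. The Alkbh5 peak of VCD spanned both CON peaks, and 1 exonic Fto peak of CON lay as 2 peaks in VCD. The counts of these 2 genes therefore show no peak lost or gained.

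**Figure D4:**
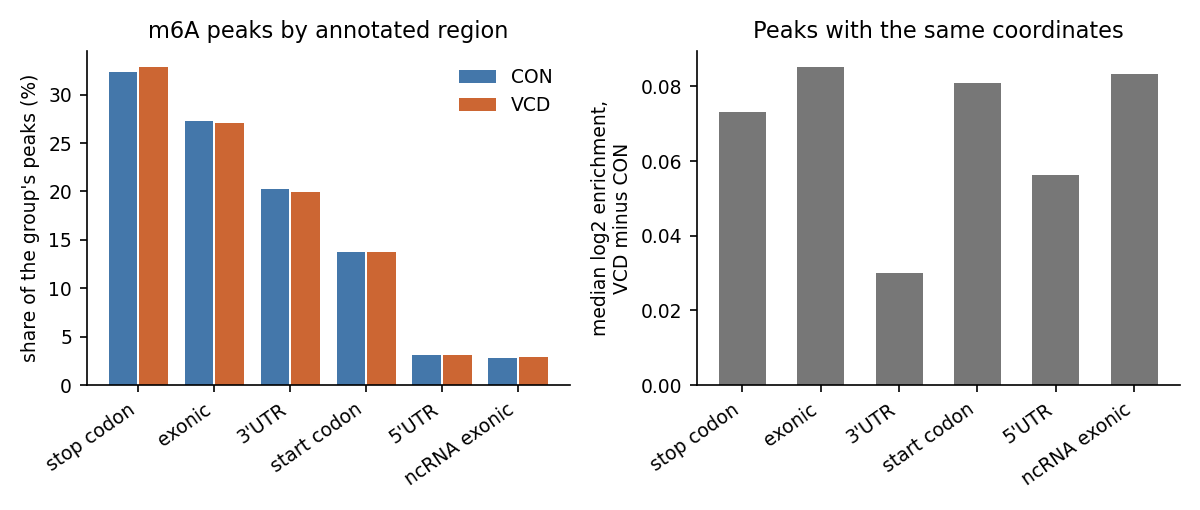
Share of m6A peaks (%) by annotated region in CON and VCD, and median difference in log2 enrichment (VCD minus CON) of the 6028 peaks with the same coordinates in both lists, 1 pooled list per group. Regional shares are alike in both groups, with stop codons at 32.4% and 32.9%, and median differences lie between 0.03 and 0.09.

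The comparison of m6A enrichment between groups rests on the authors' deposited table of differential peaks. Of the peaks in the authors' deposited table, 431 in 400 genes were marked as significant, 257 higher and 174 lower in VCD, 5 of them with no p-value. An adjusted p under 0.05 left 130 higher and 92 lower peaks in the authors' deposited table. Without a minimum fold it held 4580 higher and 948 lower peaks, and 80.1% of the 5533 peaks listed in the authors' deposited table had an absolute log2 change under 0.5. Lowering each change by the median of peaks with the same coordinates left 231 higher and 188 lower peaks of the authors' deposited table. That median, 0.068, came from the peak lists of the groups, while changes listed in the authors' deposited table had a median of 0.19. Peaks kept the p-value of the change before this step, so these 2 counts cannot decide on a shift common to all peaks.

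The peaks named next were ranked among significant ones with an adjusted p under 0.05 and a gene symbol. Pcgf1, a component of a Polycomb complex, had the largest rise among these in the authors' deposited table, a log2 change of 6.13 (adjusted p = 8.8e-27). It lay at an exonic peak on chromosome 4, 113911679 to 113912425 on the plus strand. In the authors' deposited table Myh9l1, a copy of a myosin gene, changed by 5.28 (adjusted p = 1.9e-46), Mtf1, the metal-responsive transcription factor, by 4.45 (1.2e-09), and the zinc finger genes Zfp420 by 3.61 (0.0198) and Zkscan2 by 3.60 (0.0134). The largest fall among these peaks in the authors' deposited table was at Exoc2, of the exocyst complex, a log2 change of -5.68 (adjusted p = 2.9e-23). It lay at an exonic peak on chromosome 17, 34750722 to 34770441 on the plus strand. Col15a1, a basement membrane collagen, had a log2 change of -5.25 in the authors' deposited table (adjusted p = 9.3e-18), Sccpdh of -4.65 (0.00142), Abl1, a tyrosine kinase, of -4.58 (4.6e-12) and Ccdc187 of -4.37 (0.00247). Start and end of a peak span its introns.

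Among the study's genes, a Bub1 peak at the stop codon (chromosome 3, 120374329 to 120376432, minus strand) changed by 0.75 on the log2 scale in the authors' deposited table (adjusted p = 0.0406). An Alkbh5 peak at the stop codon changed by 0.18 in the authors' deposited table (adjusted p = 0.0204). Of Polq, 2 exonic peaks in the authors' deposited table changed by 3.17 and 2.93 (adjusted p = 0.0391 and 0.0577), although the VCD list held no Polq peak. No Igf2bp3, Mettl3, Fto or Cenpa peak was listed there. In no fixed list did genes with a peak differ from other genes in the share with a higher listed peak after adjustment, the smallest adjusted p being 0.0855 for smooth muscle genes (7 of 9; Fisher's exact test).

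The last comparison asks whether the direction of the m6A change went with the direction of the expression change. Ooep, the maternal-effect gene, fell in expression by 1.62 on the log2 scale and carried a peak with a log2 change of 1.32 in the authors' deposited table (adjusted p = 2.3e-06). Nlrp5 fell in expression by 1.14 and carried a peak that changed by 2.43 in the authors' deposited table (adjusted p = 0.140). With the replicate number as a block, Nlrp5 had an adjusted expression p of 0.0620. These 2 genes and AC135142.1, named after their values were seen, were the only ones with both a significant peak and a changed transcript. Of 303 significant peaks in 279 tested genes, 39 were higher in genes with a higher value in VCD and 138 higher in genes with a lower value, while 38 and 88 were lower in such genes. The odds ratio was 0.654 (Fisher's exact test, 2-sided, p = 0.141) and Spearman's rho across peaks was -0.06, where peaks and genes are not independent replicates. Over all 5337 listed peaks in tested genes the odds ratio was 0.545 (Fisher's exact p = 8.2e-16, rho -0.22). Among the significant peaks, the 128 in genes with a mean of at least 5 FPKM gave 1.72 (Fisher's exact p = 0.197, rho 0.17). The same input libraries entered the expression change and the enrichment change.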

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

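All tests of explanations in this part were chosen only after the result was seen. In 18 of 288 groups of 4 libraries, 1 library lay far from the other 3, and chance alone does so in about 1 in 20 groups. The oocyte list's mean log2 value was 1.01 in VCD 1 against 0.81 to 0.84 in the other VCD libraries, and Igf2bp3 was 0.120 FPKM in VCD 1 and listed at 0 in the other 3. VCD 1 also stood apart in Lox (13.6 FPKM against 4.07 to 4.79), Krt7 (1.07 against 0.640 to 0.688) and Hmox1 (67.0 against 78.3 to 80.1). Other VCD libraries stood apart in Dusp16 (VCD 2, 63.9 against 55.1 to 56.0), Dusp14l1 (VCD 3, 22.5 against 19.9 to 20.2), the inflammatory list mean (VCD 3, 2.85 against 3.09 to 3.12), Tagln (VCD 4, 419 against 273 to 288), Blm (VCD 4, 0.855 against 1.35 to 1.38) and Rps6kb1 (VCD 4, 7.13 against 9.27 to 9.57). Among CON libraries these were Gadd45a (CON 1, 139 against 201 to 202), Ythdf3 (CON 3, 15.5 against 12.4 to 12.7), Lox (CON 3, 15.4 against 11.5 to 11.8), the ribosomal RNA sum (CON 3, 25.0 against 8.17 to 9.03), Runx2 (CON 4, 34.3 against 32.9 to 33.0), Blm (CON 4, 1.44 against 2.39 to 2.49) and genes with at least 1 FPKM (CON 4, 13618 against 13801 to 13835).

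The oocyte list fell by a median of 1.10 on the log2 scale. Of the 35 splits of the 8 libraries 1, the real one, gave a camera p as small (3.9e-21, against 3.4e-09 as the smallest of the others). Chance is thereby argued against but not excluded, 1 of 35 being the smallest share possible here. If the replicate number were a pairing, only the 8 splits that part the 4 pairs would count (smallest other 1.1e-06), too few for a share under 0.05. Lower detection of scarce transcripts in VCD is argued against as the whole cause, since the lowest of 10000 random lists matched on expression had a median of -0.38 against -1.10 in oocyte genes. Dilution of all follicles alike by other tissue is argued against, since the granulosa median log2 ratio of mean FPKM lay 2.40 above the oocyte median. The SD was 0.70 in granulosa genes and 1.34 in oocyte genes. A list median cannot decide on loss or dilution of small follicles alone, since Amh, of small growing follicles, fell too. Fewer oocytes may explain that 91.9% of oocyte genes had a lower VCD mean, but less RNA per oocyte would give the same share, and in bulk tissue these cannot be told apart.

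More m6A peaks were listed higher than lower in VCD, 82.8% of those in the authors' deposited table. A shift of equal size in every class as the whole cause is argued against, since medians of the regional classes differed by more than permuted classes did (permutation p = 0.0009). That permutation took peaks of the same gene as independent. It cannot decide on a common shift whose size varies with a peak's enrichment, which was not tested. Peaks in the 3' UTR had the smallest class median, and also the lowest median log2 enrichment in CON, at 1.79. A common shift as a part of the cause cannot be told apart from the treatment, since even the lowest class median was above 0, at 0.030, and each group's libraries were pooled. Lowering each listed change by the common median left 81.7% higher, which decides nothing, since peaks were listed by the p-value of the change before that step.

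Over peaks with the same coordinates in both lists, a higher m6A change went with a lower expression change (rho -0.12; -0.22 over all listed peaks, where slopes by expression level were not computed). Noise of the input libraries, which enter both measures, may be a source of this relation, since the slope was -0.16 at 2 to 5 FPKM and -0.004 at 20 to 50 FPKM, a difference of 5.05 standard errors. These errors took peaks of the same gene as independent. A relation of the same size at every expression level is argued against by that difference of 0.16. Other slopes were -0.45 below 2 FPKM, -0.046 at 5 to 10, -0.053 at 10 to 20 and -0.025 from 50 FPKM, so the slope did not shrink at every step. An effect of m6A on transcript level in scarce transcripts remains open and was not tested.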

How the results depend on the processing

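The tests of splits, and the alternatives that leave out 2 libraries, centre the m6A change or use peaks with the same coordinates, were chosen after seeing the data. The 67 changed genes (16 higher, 51 lower) became 3 (2 and 1) at a mean of at least 5 FPKM, 31 (5 and 26) with the replicate number as a block, 7 (1 and 6) without VCD 2 and VCD 4, 3 (1 and 2) without CON 2 and VCD 4, and 1038 (396 and 642) in the authors' deposited table; with no filter 10 were higher. Leaving out 1 library gave 12 to 115 genes, 3 to 27 higher and 9 to 88 lower. Of 35 splits 1 gave as many genes, the real one with 67 against 1 in the highest other. This argues against chance but does not exclude it, since 1 of 35 is the smallest share these splits can give. If the replicate number were a pairing, only the 8 splits that part the 4 numbered pairs would count, where the highest other was 0. For the 12 gene lists 2 of 35 splits gave as many, the highest other also 12, so chance cannot be excluded; among those 8 splits it was 8. So few as 8 splits cannot give a share under 0.05 for either count. Of 6 higher lists 3 passed under quantile normalization, 3 without VCD 2 and VCD 4, and 0 with an estimated correlation, where also 0 lower lists passed; directional fry gave 0 higher lists and ended the call of the stroma list among the lower ones. Fry for members in either direction gave 13 lists, among them 5 that camera had not passed: writers (0.0254), granulosa (0.0145), apoptosis (0.00578), PI3K (0.0123) and inflammatory genes (0.00474). Lists that camera had passed and this fry test had not were theca (0.0668), stroma (0.0827), smooth muscle (0.329) and NRF2 genes (0.209). The adipocyte list, which had passed at a mean log2 change of 0.022, had a mean of -0.080 without CON 4, -0.071 without VCD 4, -0.065 at a mean of at least 5 FPKM, below 0 with no filter too, -0.026 without VCD 2 and VCD 4, and -0.075 without CON 2 and VCD 4, with camera's direction still higher. Camera's or fry's direction turned in these lists, none of which had passed: meiotic prophase (mean 0.10 at a mean of at least 5 FPKM, -0.021 under quantile normalization), and, while the mean stayed below 0, apoptosis (-0.036 at a mean of at least 5 FPKM; without VCD 2, in a range of -0.12 to -0.060), macrophage (without CON 3 and without CON 4, range -0.19 to -0.035) and granulosa (without VCD 3, range -0.31 to -0.064); and xenobiotic metabolism, which fry put lower at the same mean of 0.015. Genes that changed sign, none of them called, were Mettl3 (without CON 4 and without VCD 2, range -0.016 to 0.070; -0.040 without VCD 2 and VCD 4), Alkbh5 (without VCD 1, range -0.020 to 0.058), Fto (without VCD 1, range -0.013 to 0.10), Hba-a1 (without VCD 1, range -0.13 to 0.60; -0.15 without VCD 2 and VCD 4) and Hba-a2 (without VCD 3, range -0.84 to 0.014). The replicate number as a block changed no list call, and no call of a named gene beyond those given with the results. For named genes, 804 of 893 values under other settings and 826 of 928 with 1 library left out kept direction and side of the threshold. A fold enrichment of at least 4 left 13635 CON and 13934 VCD peaks, of which 93.9% and 96.6% were shared; shares were 87.5% and 91.2% with overlap of at least 50% of the shorter peak, and 76.4% and 79.2% with that of both. Differential peaks in the authors' deposited table were 130 higher and 92 lower at an adjusted p under 0.05, and 4580 and 948 with no minimum fold. The odds ratio of m6A and expression directions was 0.545 (rho -0.22) over all listed peaks, 1.72 (rho 0.17) over significant peaks in genes with a mean of at least 5 FPKM and 0.721 (rho -0.12) over peaks with the same coordinates. The cause of these changes was not tested. Count tests (edgeR, DESeq2) were not run for want of counts, nor a fit with the IP libraries, whose expression values were not used here. Without read totals, depth could not be set against these values.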

Other observations

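The gene lists of this part, and their tests, were chosen only after the data were seen, so their p-values describe a pattern already noticed. Immediate-early genes were higher in value in 19 of 19 (median log2 change 0.69, camera with limma adjusted p = 8.8e-12; adjusted p = 0.194 with an estimated correlation), and 1, Nr4a3, rose over all genes. Their mean log2 value was 5.20, 4.35, 3.85 and 5.21 in VCD 1 to 4 and 4.02, 3.77, 4.13 and 3.48 in CON 1 to 4, so VCD 3 lay within the CON range. Motile cilium genes had a median log2 change of -0.57 (11 tested; camera with limma adjusted p = 0.00251; adjusted p = 0.347 with an estimated correlation), and their mean was highest in CON 2, at 2.06.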
